A study of Mus musculus with 67 samples.

How the data were processed

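RNA from the lungs of female C57BL/6 mice that received Printex 90 carbon black nanoparticles or vehicle through the trachea was hybridised to 67 Agilent mouse arrays with 45018 spots each. Each array carried RNA of a single mouse in the Cy5 channel and a universal mouse reference RNA in the Cy3 channel, per the labels, so that every array had the same dye orientation. The labels give 12 groups: 0, 18, 54 or 162 µg of particles, each on days 1, 3 and 28 after the instillation. Of these, 5 groups held 5 mice (the controls of days 1 and 28, 54 µg on days 3 and 28, and 162 µg on day 28) and the others held 6. The labels give no replicate numbers, so replicates were numbered in the order of the records, and no paired analysis was possible because nothing in the labels pairs treated with control mice.

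The deposited scanner files hold intensity values for each spot and channel: median signals, median local backgrounds, Agilent's processed signals, and flags for spots well above background, for saturated spots and for uneven spots or backgrounds (other data, per the file headers). They were made with an Agilent scanner and Feature Extraction, under an older protocol on 22 arrays and a newer one on 45, per the file headers. The deposited value table holds log2 ratios of Cy5 over Cy3 normalized by the authors, with medians between -0.05 and -0.02 per array; the normalization method was not given in the sources used here. The authors' values correlated with the unprocessed log2 ratios at r between 0.727 and 0.995 per array, and with the values computed here at r between 0.991 and 0.996, over probes.

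From the scanner files, spots with an uneven signal or background (68 to 223 per array) were set to missing. Signals were corrected for background by normexp with an offset of 50, log2 ratios were normalized within each array by loess, and spots of the same probe were averaged. The plan named mean signals, and the files hold medians with median backgrounds, which were used. Uneven spots were removed before the background correction after 7 arrays were seen to give failed corrections with them. An alternative kept them for the correction and then left out spots with an uneven signal. Spots with only an uneven background stayed in throughout, so that alternative differs in the spots used as well as in the order. A probe was kept when its Cy5 signal was well above background on at least 3 arrays of at least 1 group, which left 27273 of 41174 probes and 696 missing values. For each gene the probe with the highest mean Cy5 signal was used, which gave 21238 genes, 13497 of them with a symbol. Symbols were taken through the RefSeq identifiers of the probes; no positions are given because the array names an older mouse assembly than the reference table.

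The share of spots with a Cy5 signal well above background was 51.3 to 75.0% per array, with median Cy5 signals of 109 to 218.5 over backgrounds of 82 to 98.5, and no spot was saturated. For arrays, their number per group limits the precision; limma found a median residual SD of 0.17 on the log2 scale with 55 residual degrees of freedom.

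A linear model with a mean for each of the 12 groups was fitted with limma 3.58.1 under R 4.3.3, with empirical Bayes moderation, and 15 comparisons were read from it. Genes passed at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, two-sided. The comparisons were each dose with the control of its day, 162 with 54 µg on each day, the difference of the 162 µg effect between days (interaction tests), and the controls of day 28 with those of day 1. In total, 32 gene lists for lung cell types, inflammation, metabolism and stress were written before the data were examined, as were the groups, the tests, the rule for named genes and 20 of the alternatives. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the data; fry was an alternative. A list's p was adjusted over the lists of its comparison. Passing members were also counted with p adjusted over the list alone. A list's shift is the mean log2 change of its measured members, with an error from the same model applied to the list's mean on each array. The relations across arrays used deviations from group means and 100000 permutations.

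By the rule for named genes, each comparison of 162 µg with control names up to 8 rises and 6 falls, the largest among genes that passed with every treated array on the same side of the control median and that were well above background in both groups. It adds up to 5 genes not well above background on any array of one group, with the largest lower bound of their fold, and up to 3 passing members of each list. For 54 and 18 µg it names 5 rises and 3 falls and gives the values of the genes named for 162 µg; for other tests it names up to 4 in each direction. Only genes with symbols were named. A lower bound, written as at least a given fold, sets the bright group's mean over all its arrays against the dim group's mean, where each dim array counts with the higher of its own signal and the lowest signal well above background on it. Bounds are of the Cy5 signal alone, not of the ratio, and so can lie above the fold of the ratios. They are estimates from group means, with no allowance for the spread between mice. Where every dim array's own signal is the higher, as for Cxcl5 on day 1, the bound is the plain fold of the Cy5 means. Bounds use the Cy5 channel after loess and quantile normalization between arrays of the average log intensity of both channels. Without dye swaps they stay open to dye bias.

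The 18 slides held arrays of more than one group each and were scanned on 10 days. Slide as a fixed or random block, scan day and protocol as blocks, differences within slides, no background correction, Agilent's processed signals, median centring, the authors' values, other filters and thresholds, array weights, all probes, only the compared groups, and each mouse left out in turn were alternatives. A further 5 were added after the data were seen: the uneven spots kept for the background correction, each protocol's arrays alone, and fits without the slide scanned first, without the 7 arrays named above, or without the 5 arrays with the highest heart muscle signal. Quantile normalization of the average log intensity of both channels leaves the ratios unchanged, so that alternative tested nothing. List tests were not run with slide as a random block, with a fold threshold, or within the older protocol where a group had fewer than 2 arrays. The model was tested on simulated data with independent noise of each gene's own spread and known shifts in one group. In 7 comparisons, a shift of 1 was recovered for 92.5 to 100% of genes and one of 0.5 for 64.2 to 79.1%, and 2.66 to 7.25% of calls were false; a list shifted by 0.5 was called in each, and 1 other list once. Python 3.11.15, the R package data.table at version 1.17.8 and matplotlib 3.10.9 were used for tables and figures. Other files of the series were not used here.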

Results

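Gene expression was measured in the lungs of 67 female mice on 2-colour arrays. The mice had received carbon black nanoparticles (Printex 90), an industrial soot-like powder, at 18, 54 or 162 µg, or vehicle alone, through the trachea 1, 3 or 28 days earlier. The 12 groups of day and dose held 5 or 6 mice each. The Cy5 signal of the lung RNA was well above background for 51.3 to 75.0% of spots per array, and 21238 genes were tested. Values are log2 changes of the ratio of lung to reference RNA, with the standard error (SE) of limma's fit. For arrays, the number of mice per group limits the precision. The comparisons ask which genes of the lung responded to the particles, at which dose, and for how long.

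On day 1, the lungs of mice given 162 µg (n = 6, against 5 controls) showed much higher levels of acute phase and chemokine messages. Saa3, a serum amyloid A made outside the liver, rose by 6.07 ± 0.72, which is 67.4-fold. Its relatives Saa1 and Saa2 rose 14.8-fold (3.89 ± 0.45) and 6.94-fold (2.79 ± 0.34). Timp1, an inhibitor of matrix metalloproteinases, rose 13.9-fold (3.80 ± 0.43), and Lcn2, a lipocalin that binds bacterial iron carriers, rose 6.09-fold (2.61 ± 0.43). The metallothionein gene Mt2 rose 5.66-fold (2.5 ± 0.31), and the monocyte chemoattractants Ccl7 and Ccl2 rose 5.55-fold (2.47 ± 0.42) and 5.32-fold (2.41 ± 0.38). The adjusted p of these 8 genes lay between 2.15e-08 and 9.34e-05, and each was higher than the control median on 6 of 6 arrays.

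The 6 largest falls on day 1 at 162 µg were smaller. Bcan fell by 1.1, Igfbp3 by 1.09, Fbln1 (a matrix protein) by 0.98, Fabp1 (a fatty acid binding protein) by 0.94, Hes2 by 0.91 and Mamdc2 by 0.90. Each was lower on 6 of 6 arrays, with an adjusted p between 0.000162 and 0.0234. The chemokine gene Cxcl5, a neutrophil attractant, was not well above background on any control array and was so on 6 of 6 treated arrays, at least 3.51-fold higher in Cy5 signal (adjusted p = 0.0242). Further lower bounds of the Cy5 signal were at least 1.66-fold for Serpina3f (adjusted p = 0.000135, 6 arrays), 1.34-fold for Fgl1 (0.0105, 5 arrays) and 1.33-fold for Retnlb (0.0247, 4 arrays). By their ratios these 4 genes were 3.49-fold, 1.6-fold, 1.29-fold and 1.25-fold higher, below the bounds of the Cy5 signal. The bounds, here and below, make no allowance for the spread between mice.

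In all, 991 genes passed on day 1 at 162 µg by limma, 611 higher and 380 lower. An unadjusted p below 0.05 was found for 3836 genes, and 929 passed with slide as a block (513 higher, 416 lower). The count was 1828 with Agilent's processed signals (937 higher, 891 lower), 72 with median centring (69 higher, 3 lower), 295 with uneven spots kept for the background correction, 643 without control replicate 4, 613 without the 7 arrays with uneven backgrounds and 506 when only these groups entered the fit. Within the older protocol, with 2 arrays against 1, it was 3, and Fbln1 turned to 0.0477. With slide as a block, 13 of the 50 genes chosen by the rule for named genes lost the threshold. Among them were Cxcl5 (0.105), Retnlb (0.209), Il1b (0.0607), Cfb (0.0732), Cfi (0.146) and Retnlg (0.174), with their adjusted p. Cxcr2 (0.224), Arg1 (0.057), Tk1 (0.174), Egr2 (0.102) and Junb (0.0625) lost it too.

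Among the gene lists on day 1 at 162 µg, acute phase genes rose most. Of 17 measured members, 13 rose and 4 did not pass (15 higher when adjusted over the list alone). Orm2 (1.93), Cp (1.81) and Fgg (1.57) were among them. Their mean change was 1.72 ± 0.22, 1.53 ± 0.25 with slide as a block and 1.39 to 1.81 within the 3 slides that held both groups. The list passed with adjusted p = 5.72e-28, and with adjusted p = 0.000716 with an estimated correlation. CC chemokines followed, with 11 of 17 higher (11 higher and 2 lower when adjusted over the list alone). Examples were Ccl24 (2.18 ± 0.33, 4.53-fold), Ccl4 (1.25) and Ccl12 (1.13). The mean change of CC chemokines was 0.87 ± 0.14, 0.76 ± 0.16 with slide as a block and 0.68 to 0.93 within slides. Their adjusted p = 6.26e-10 stood beside adjusted p = 0.00527 with an estimated correlation. These were the lists of this comparison whose calls held with an estimated correlation.

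Other immune lists passed with the preset correlation alone. CXC chemokines had 5 of 12 members higher (also 5 when adjusted over the list alone), with Cxcl10 at 1.86 and Cxcl1 at 1.76. The size for Cxcl1 depended on the processing and ran from 1.36 to 3.65 over the other fits. CXC chemokines as a list had adjusted p = 0.00114, and adjusted p = 0.114 with an estimated correlation. Inflammatory cytokines had 5 of 15 higher (6 when adjusted over the list alone), with Il33 at 1.53, Il1b at 1.18 and Il6 at 1.04. The value of Il6 ran from 0.75 to 3.80 over the other fits. The cytokine list had adjusted p = 0.00163, and adjusted p = 0.0754 with an estimated correlation. Of 18 neutrophil markers, 3 rose, namely Il1r2 (1.35), Retnlg (1.01) and Cxcr2 (0.91), and 1 fell (10 and 1 when adjusted over the list alone). Neutrophil markers had a mean of 0.49 ± 0.14, or 0.32 ± 0.13 with slide as a block (adjusted p = 1.85e-05, and adjusted p = 0.114 with an estimated correlation). Macrophage markers had 5 of 18 higher, including Cd14 (1.74), Msr1 (0.82) and Arg1 (0.80), or 7 higher and 1 lower when adjusted over the list alone. As a list they had adjusted p = 2.29e-05, and adjusted p = 0.114 with an estimated correlation. Complement genes had 3 of 17 higher, C3 (1.01), Cfb (0.69) and Cfi (0.59), and 4 when adjusted over the list alone (adjusted p = 0.0267, and adjusted p = 0.535 with an estimated correlation).

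Stress and matrix genes moved too on day 1 at 162 µg. Of 20 oxidative stress and metallothionein genes, 5 rose and 2 fell (6 and 2 when adjusted over the list alone). Gclc, which makes a precursor of glutathione, stood at 1.16 and Mt1 at 1.13 (adjusted p = 0.000384 for the list, and adjusted p = 0.0754 with an estimated correlation). Of 20 extracellular matrix and remodelling genes, 6 rose, led by Timp1, Tnc (0.92) and Tgfbi (0.81), and 1 fell (7 and 1 when adjusted over the list alone). The matrix list had adjusted p = 0.000117, and adjusted p = 0.114 with an estimated correlation. Glucocorticoid response genes had 2 of 11 higher (5 when adjusted over the list alone). These 2, Lcn2 and Mt2, are also in the acute phase and metallothionein lists (adjusted p = 6.42e-05, and adjusted p = 0.114 with an estimated correlation).

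Further lists passed on day 1 at 162 µg with the preset correlation alone. The cell cycle list had 2 of 27 higher (3 when adjusted over the list alone), the replication genes Mcm2 (0.69) and Tk1 (0.58). Cell cycle genes had adjusted p = 6.57e-06, and adjusted p = 0.444 with an estimated correlation. Sterol synthesis had 1 of 20 higher, Sqle at 0.73, and 9 when adjusted over the list alone (adjusted p = 3.77e-05, and adjusted p = 0.182 with an estimated correlation). Immediate early genes had 2 of 15 higher, Egr2 (0.76) and Junb (0.64), also 2 when adjusted over the list alone (adjusted p = 0.0483, and adjusted p = 0.535 with an estimated correlation). T cell and NK cell markers had 0 of 15 past the test with a mean of -0.20, also 0 when adjusted over the list alone (adjusted p = 0.00216, and adjusted p = 0.269 with an estimated correlation).

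The remaining lists did not pass on day 1 at 162 µg. The p53 and DNA damage response list (adjusted p = 0.832) had 2 of 20 members higher, with Gadd45g at 1.29, and 3 lower. Among the lower ones, Bbc3, a p53 target that promotes cell death, fell by 0.75. Single members passed in Pdpn (0.43) of alveolar type 1 markers (adjusted p = 0.786), Tekt2 (-0.53) of ciliated cell markers (0.38) and Abcg1 (-0.74) of fatty acid synthesis and lipid handling (0.572). Of secretory airway markers (adjusted p = 0.123) Pigr passed, at 1.66 but at -0.12 with Agilent's processed signals, and lost the threshold with slide as a block (adjusted p = 0.144). No member passed of aryl hydrocarbon receptor targets (mean 0.04, adjusted p = 0.575), interferon response (0.11, 0.326) or antigen presentation and dendritic cell markers (-0.01, 0.832). Nor did any of B cell and plasma cell markers (-0.04, 0.807), eosinophil and mast cell markers (-0.10, 0.807), alveolar type 2 markers (-0.01, 0.832) or endothelial markers (-0.10, 0.331). The same held for heart muscle (0.23, or -0.26 without 162 µg replicate 1, 0.611), skeletal muscle (0.09, 0.824) and adipose markers (-0.07, 0.832) and the circadian clock (-0.03, 0.723). Erythroid and thymus markers had 3 measured members each, none past the test, with means of -0.13 and -0.08. Mean and median differed in sign for fatty acid synthesis (0.00 and -0.08), eosinophil and mast cell markers (median 0.01) and adipose markers (median 0.13), whose tests pointed down.

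**Figure D1:**
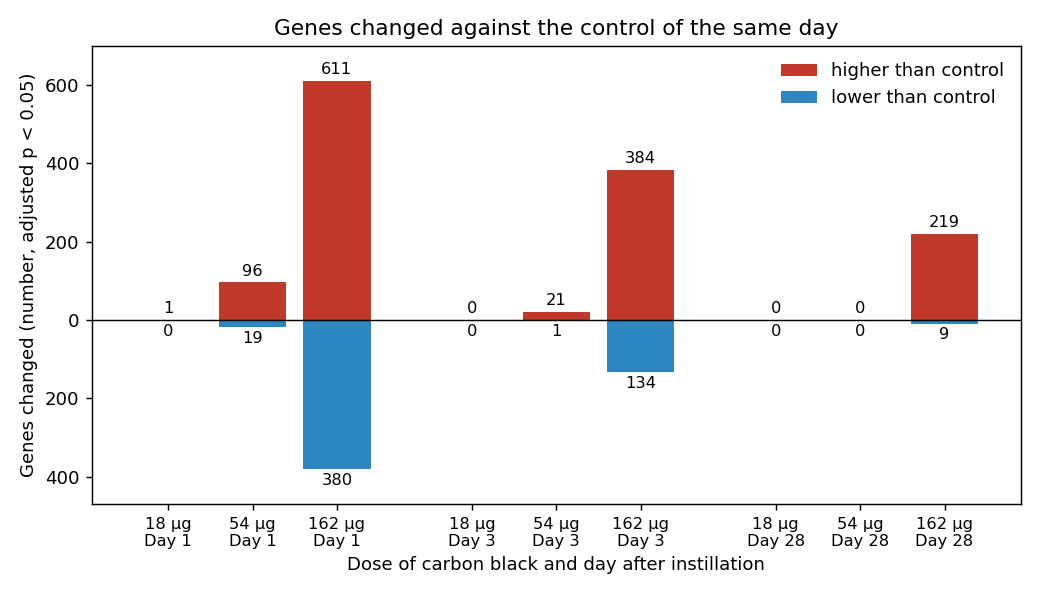
Number of genes past an adjusted p of 0.05 (y axis, genes) at each dose and day (x axis), with bars above 0 for genes higher and below 0 for genes lower than the control of that day. At 162 µg the bars reach 611 and 380 genes on day 1, 384 and 134 on day 3, and 219 and 9 on day 28.

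At 54 µg on day 1 (n = 6, against 5), Saa3 rose 25.3-fold (4.66 ± 0.72, adjusted p = 0.000246) and Timp1 5.08-fold (2.35 ± 0.43, 0.00218). Each lay above the control median on 6 of 6 arrays. On replicate 6, however, Saa3 had a log2 ratio of -2.51, close to the control mean, against 2.01 to 3.98 on the other arrays. Cxcl10 (1.64 ± 0.39, 0.0285), Ccl8 (1.51 ± 0.32, 0.0135) and Ch25h, an enzyme that oxidises cholesterol (1.45 ± 0.28, 0.0032), also rose on 6 of 6 arrays. Of the genes named at 162 µg, Saa1 rose 7.5-fold (2.91 ± 0.45), Lcn2 4.39-fold (2.13 ± 0.43) and Saa2 3.62-fold (1.86 ± 0.34). Their adjusted p was up to 0.00583, and 5 of 6 arrays lay above the control median. Cox7a2l fell by 0.54, Ube2b by 0.47 and Mid1ip1 by 0.44 (adjusted p of 0.0032, 0.028 and 0.0459). Cxcl10 (adjusted p = 0.0811), Ccl8 (0.0955), Ch25h (0.0606) and Mid1ip1 (0.0607) lost the threshold with slide as a block. C3 (1.2), Cd14 (1.19), Retnlg (1.28), Cxcr2 (1.26), Il1r2 (1.1) and Cfb (0.77) also passed. Serpina3f was at least 1.4-fold higher in Cy5 signal, on 5 of 6 arrays (adjusted p = 0.0114). Mt2 (0.95, adjusted p = 0.148), Ccl7 (1.25, 0.16), Ccl2 (1.08, 0.198) and Cxcl5 (adjusted p = 0.218) did not pass.

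Among 18 neutrophil markers at 54 µg on day 1, 5 rose, such as S100a8 (1.53) and Mmp8 (1.05), and 10 when adjusted over the list alone. Their mean was 0.66, 0.53 ± 0.14 with slide as a block and 0.28 to 0.54 within 2 slides (adjusted p = 3.73e-12, and adjusted p = 0.0141 with an estimated correlation). Acute phase genes had 9 of 17 higher (12 when adjusted over the list alone), with a mean of 1.19, or 1.04 ± 0.26 with slide as a block. CC chemokines had 2 of 17 higher (9 when adjusted over the list alone), with a mean of 0.58. Both lists had adjusted p = 0.0141 with an estimated correlation. Extracellular matrix genes had 1 of 20 higher (7 when adjusted over the list alone), with a mean of 0.42 and adjusted p = 0.0377 with an estimated correlation. The interferon response list had 1 of 18 higher, Gbp2 at 0.43, and 6 when adjusted over the list alone (adjusted p = 6.94e-10, and adjusted p = 0.104 with an estimated correlation).

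The test at 54 µg on day 1 passed 115 genes, 96 higher and 19 lower (2575 at an unadjusted p below 0.05, and 138 with slide as a block). The count ranged from 33 without 54 µg replicate 2 to 365 without 54 µg replicate 6, whose Saa3 and Lcn2 levels lay far below those of its group. It was 19 with median centring, 31 with uneven spots kept, 243 in the newer protocol and 0 in the older protocol and when only these groups entered the fit.

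At 18 µg on day 1 (n = 6, against 5), Gnal, a G protein subunit gene, was the only gene past the test. It was higher by 0.51 ± 0.10 (1.42-fold, adjusted p = 0.0388), on 6 of 6 arrays. Saa3 (2.12 ± 0.72, adjusted p = 0.391), Saa1 (1.16 ± 0.45, 0.52), Timp1 (1.00 ± 0.43, 0.604) and Lcn2 (0.94, 0.646) did not pass. Acute phase genes had a mean of 0.47 (0.28 without 18 µg replicate 4), with 0 of 17 past the test and also 0 when adjusted over the list alone (adjusted p = 0.000156, and adjusted p = 0.364 with an estimated correlation). Glucocorticoid response genes had a mean of 0.73, with 0 of 11 past the test and 4 when adjusted over the list alone (adjusted p = 6.56e-07, and adjusted p = 0.175 with an estimated correlation). The count of 1 gene (1528 at an unadjusted p below 0.05) became 0 to 9 without single mice and 26 with slide as a block.

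Between 162 and 54 µg on day 1 (n = 6 each), Ccl24, an eosinophil attractant, was 3.08-fold higher at the larger dose (1.62 ± 0.31, adjusted p = 0.00849). Mt2 was 2.93-fold higher (1.55 ± 0.29, 0.00843), Pbp2 2.51-fold (1.33 ± 0.17, 2.42e-06) and Sprr1a, a cornified envelope gene, 2.47-fold (1.31 ± 0.20, 0.000136). In all, 19 genes passed, 18 higher and 1 lower (1820 at an unadjusted p below 0.05, and 40 with slide as a block). The acute phase list had a mean of 0.53 (0.26 without 54 µg replicate 6) with 0 of 17 past the test and 3 when adjusted over the list alone (adjusted p = 1.35e-07, and adjusted p = 0.206 with an estimated correlation). The interferon response list had a mean of -0.31 with 0 past the test and 3 lower when adjusted over the list alone (adjusted p = 1.35e-07, and adjusted p = 0.385 with an estimated correlation). The count ran from 5 without 54 µg replicate 4 to 38 without 162 µg replicate 2, and was 0 when only these groups entered the fit.

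On day 3, the response to 162 µg (n = 6 each) held inflammation genes together with genes of cell division and sterol synthesis. Saa3 was 8.74-fold higher (3.13 ± 0.69, adjusted p = 0.00653), and Slc26a4, which encodes the anion exchanger pendrin, 6.35-fold (2.67 ± 0.43, 0.000137). Lcn2 rose 5.27-fold (2.40 ± 0.41, 0.000274) and Spp1, the gene of osteopontin, 3.56-fold (1.83 ± 0.41, 0.00819). Ccl2 rose 3.41-fold (1.77 ± 0.37), Ly6f 3.25-fold (1.70 ± 0.40), Noxo1, an organizer of an NADPH oxidase, 3.22-fold (1.69 ± 0.30) and Ccl7 3.18-fold (1.67 ± 0.40). Their adjusted p was up to 0.0125, and each of the 8 genes was higher on 6 of 6 arrays. Pon1 fell by 0.94, Rgs2, a regulator of G protein signalling, by 0.90, Zfp503 by 0.89, Tfap4 by 0.75 and Mylip by 0.74. These had an adjusted p between 0.000466 and 0.0292 and were lower on 6 of 6 arrays. Cxcl5 was not well above background in any control and was at least 4.99-fold higher in Cy5 signal (adjusted p = 0.00613, 4.61-fold by its ratio). This bound was at least 1.51-fold for Mmp12 (1.44-fold by its ratio), the macrophage elastase (adjusted p = 0.0204), 1.46-fold for Cxcl3 (0.032) and 1.16-fold for Retnlb (0.048, well above background on 1 of 6 arrays).

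Of 27 measured cell cycle genes, 16 rose on day 3 at 162 µg and 0 fell (24 rose when adjusted over the list alone). The mitosis genes Kif20a (1.30 ± 0.23, 2.46-fold), Cdc20 (1.28 ± 0.26) and Birc5 (1.2 ± 0.25) led. The list's mean change was 0.67 ± 0.16, 0.63 ± 0.19 with slide as a block and 0.38 to 0.53 within 3 slides. Its adjusted p = 8.1e-22 became adjusted p = 0.0632 with an estimated correlation. Of 20 sterol synthesis genes, 11 rose and 0 fell (15 rose when adjusted over the list alone). Sqle (0.89 ± 0.15, 1.85-fold), Hmgcs1 (0.82 ± 0.19) and Fdps (0.73 ± 0.16), all enzymes of the cholesterol pathway, were among them. Sterol genes had a mean of 0.43 ± 0.08, 0.38 ± 0.09 with slide as a block and 0.24 to 0.58 within slides. As a list they had adjusted p = 3.38e-16, and adjusted p = 0.0187 with an estimated correlation.

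Macrophage markers had 7 of 18 higher on day 3 at 162 µg, including Cd14 (1.66 ± 0.26), Ctsk (1.43 ± 0.26) and Gpnmb (1.04), and 9 when adjusted over the list alone. Their mean was 0.58 (adjusted p = 1.44e-09, and adjusted p = 0.0511 with an estimated correlation). CC chemokines had 6 of 17 higher, with Ccl8 at 1.18, or 8 higher and 1 lower when adjusted over the list alone. Their mean was 0.56 (adjusted p = 1.39e-05, and adjusted p = 0.0632 with an estimated correlation). Acute phase genes had 3 of 17 higher, with Cp at 1.2, and 7 when adjusted over the list alone (adjusted p = 0.000153, and adjusted p = 0.336 with an estimated correlation). Extracellular matrix genes had 3 of 20 higher, with Timp1 at 1.46 and Mmp14 at 0.75, and 6 when adjusted over the list alone (adjusted p = 1.56e-05, and adjusted p = 0.104 with an estimated correlation). CXC chemokines had 4 of 12 higher, among them Cxcl10 (1.53) and Cxcl1 (1.04), and 5 when adjusted over the list alone (adjusted p = 0.00738, and adjusted p = 0.225 with an estimated correlation).

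Lymphocyte lists pointed down on day 3 at 162 µg. T cell and NK cell markers had 1 of 15 lower, Lck (-0.44), a kinase of T cells, and 5 when adjusted over the list alone. Their mean was -0.22 (adjusted p = 9.7e-05, and adjusted p = 0.179 with an estimated correlation). B cell and plasma cell markers had 0 of 11 past the test and 3 lower when adjusted over the list alone, with a mean of -0.25 (adjusted p = 0.00176, and adjusted p = 0.336 with an estimated correlation). Single members passed in lists that did not. They were Gclc (1.22), Mt2 (1.14) and Mt1 (0.79) of the oxidative stress list (adjusted p = 0.0762), and Sesn1 (-0.52) and Xpc (-0.39) of the p53 list (0.7). Il33 (1.11) and Il1rn (0.70) of the cytokine list (adjusted p = 0.0934) and Mmp8 (0.73) of the neutrophil list (0.0929) passed too. So did Ifit1 (1.03) of the interferon list, Atf3 (0.77) of the immediate early list, and Pigr, at 1.44 but at -0.40 with Agilent's processed signals. Pigr lost the threshold with slide as a block (adjusted p = 0.155).

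The day 3 test at 162 µg passed 518 genes, 384 higher and 134 lower (3579 at an unadjusted p below 0.05, 673 with slide as a block and 986 with scan day). The count was 140 without 162 µg replicate 4, 175 without 162 µg replicate 2, 293 without control replicate 2 and 331 without control replicate 3. It was 45 with median centring, 46 within the newer protocol, 0 within the older one, 191 with uneven spots kept, 319 without the 7 arrays with uneven backgrounds and 801 with Agilent's processed signals (506 higher, 295 lower). Of the 46 genes chosen by the rule, 17 lost the threshold with slide as a block. Spp1 then stood at 1.45 ± 0.46 (adjusted p = 0.065) and Mmp12 had an adjusted p of 0.0695. The others included Ccl7 (0.0701), Zfp503 (0.0685), Cxcl3 (0.0985), Retnlb (0.17), Cp (0.064), Cxcl1 (0.0732) and Ccl8 (0.0783). The same held for Mmp8 (0.104), Mt2 (0.144), Mt1 (0.0525), Fdps (0.0542), Timp1 (0.138) and Lck (0.0632).

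At 54 µg on day 3 (n = 5, against 6), Slc26a4 was 5.37-fold higher (2.43 ± 0.45, adjusted p = 0.00462), and Lcn2 3.95-fold (1.98 ± 0.43, 0.0306). Ch25h rose 3.05-fold (1.61 ± 0.28, 0.00122), Noxo1 2.97-fold (1.57 ± 0.31, 0.0118) and Wfdc21 2.87-fold (1.52 ± 0.29, 0.00658). Rgs2 fell by 0.83 (adjusted p = 0.0162, and 0.0525 with slide as a block), and Cxcl5 was at least 5.39-fold higher in Cy5 signal on 5 of 5 arrays (0.0393, 4.76-fold by its ratio). Cd14 (1.33) and Ctsk (1.33) passed as well, while Saa3 stood at 2.56 ± 0.72 with an adjusted p of 0.216. Macrophage markers had 2 of 18 higher (8 when adjusted over the list alone), with a mean of 0.53, 0.52 with slide as a block and 0.25 to 0.33 within 2 slides. As a list they had adjusted p = 6.01e-14, and adjusted p = 0.0112 with an estimated correlation. Cell cycle genes had a mean of 0.38, with 0 of 27 past the test and 10 higher when adjusted over the list alone (adjusted p = 5.8e-11, and adjusted p = 0.265 with an estimated correlation). In all, 22 genes passed, 21 higher and 1 lower (1515 at an unadjusted p below 0.05, and 68 with slide as a block). The count ran from 6 without 54 µg replicate 2 or 5 to 31 over the mice left out in turn, and was 4 with median centring and 1 within the newer protocol.

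At 18 µg on day 3 (n = 6 each), limma passed 0 genes, with 802 at an unadjusted p below 0.05. Saa3 stood at 1.39 ± 0.69, Slc26a4 at 1.33 ± 0.43 and Lcn2 at 1.13 ± 0.41, each with an adjusted p of 1. Sterol synthesis genes had a mean of 0.25 with 3 of 20 higher when adjusted over the list alone (adjusted p = 3.02e-12, and adjusted p = 0.0719 with an estimated correlation). Secretory airway and heart muscle markers had means of 0.75 and 0.54 (adjusted p of 0.00174 and 0.0189, and adjusted p = 0.769 for both with an estimated correlation). Without 18 µg replicate 4 these means were 0.41 and 0.17. Between 162 and 54 µg on day 3 the count was also 0 by limma (1063 at an unadjusted p below 0.05). The cell cycle mean of that comparison was 0.29 (adjusted p = 2.35e-09, and adjusted p = 0.341 with an estimated correlation).

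**Figure D2:**
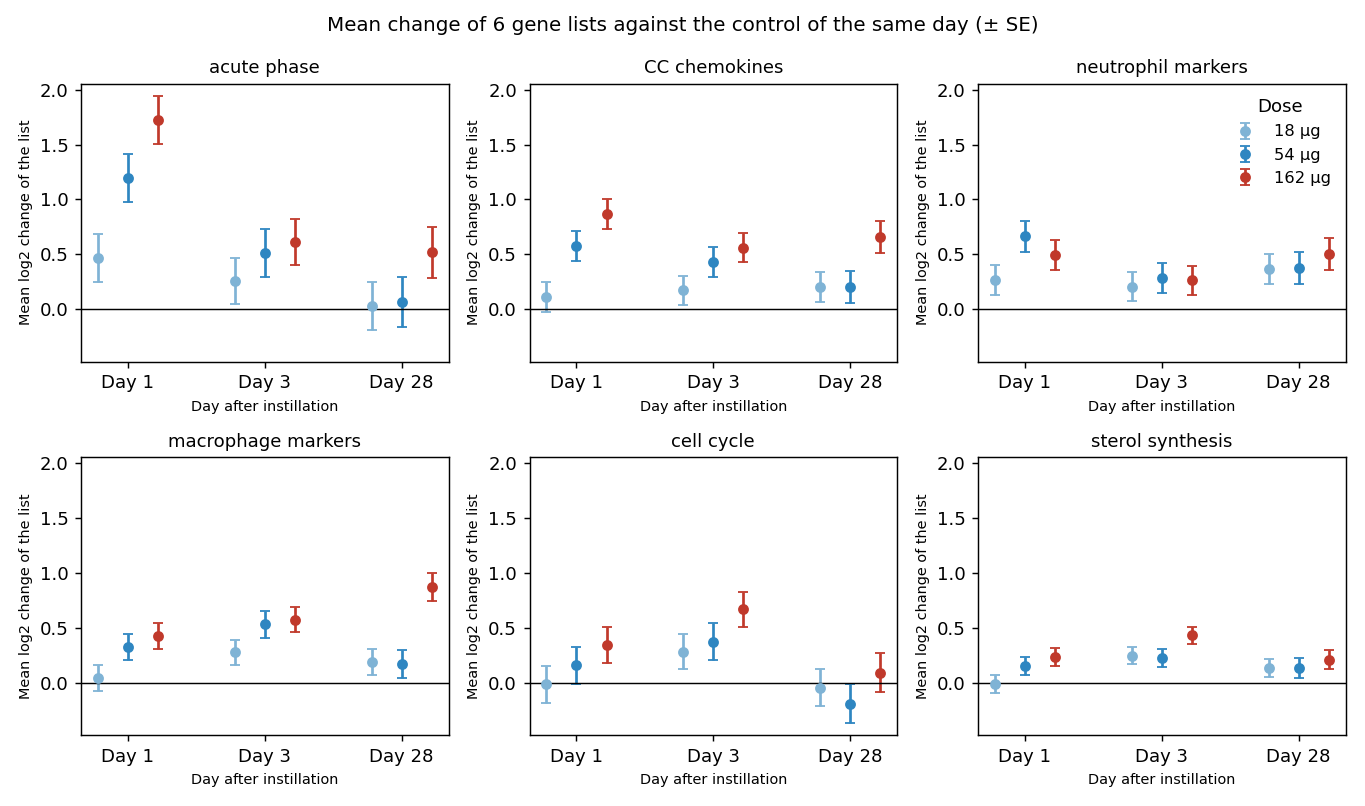
Mean log2 change of 6 gene lists (y axis) against the control of the same day, by day (x axis) and dose (colour), where points are estimates and bars their SE. At 162 µg the acute phase mean is 1.72 on day 1 and 0.52 on day 28, the cell cycle mean is 0.67 on day 3, and the macrophage mean is 0.87 on day 28.

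On day 28, macrophage genes were the main group higher after 162 µg (n = 5 each). Gpnmb, a glycoprotein of macrophages, rose 3.85-fold (1.94 ± 0.22, adjusted p = 5.47e-08), and Spp1 4.93-fold (2.30 ± 0.45, 0.00212). Trem2, a lipid receptor of macrophages, rose 2.9-fold (1.53 ± 0.24, 0.000106), while Mmp12 was at least 2.15-fold higher in Cy5 signal and 2.02-fold by its ratio (2.2e-05). Over 32 other fits the log2 change of Mmp12 ran from 0.21 to 2.77, and its call was lost in 1. Saa3 was 7.05-fold higher (2.82 ± 0.76, adjusted p = 0.0449), Slc26a4 6.07-fold (2.60 ± 0.47, 0.000574) and Lcn2 5.04-fold (2.33 ± 0.45, 0.00141). Wfdc17 was 3.82-fold higher (1.94 ± 0.31, 0.000113), Ccl2 3.67-fold (1.88 ± 0.40, 0.0061) and Noxo1 3.52-fold (1.82 ± 0.33, 0.000574). Each of these was higher on 5 of 5 arrays. The Saa3 call was kept in 15 of 32 other fits, whose values ran from 0.99 to 3.48, and lost in 17. Such tallies include an adjusted p below 0.1 and quantile normalization between arrays, under which no call could be lost. Falls were few and had an adjusted p from 0.0141 to 0.0498. Mmp3 fell by 0.72, Tspan13 by 0.61, the endothelial receptor genes Calcrl by 0.60 and Flt1 by 0.47, Med1 by 0.49 and Ndst1 by 0.45. Slfn4, not well above background in any control, was at least 1.57-fold higher in Cy5 signal (adjusted p = 0.0223, 1.56-fold by its ratio). Likewise, this bound was at least 1.44-fold for Proz (0.0131, 3 of 5 arrays), 1.23-fold for Ccdc122 (0.0243, 2 arrays) and 1.22-fold for Kcnj10 (0.0419, 3 arrays).

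Of 18 measured macrophage markers, 10 rose on day 28 at 162 µg and 8 did not pass (13 higher when adjusted over the list alone). Their mean was 0.87 ± 0.13, 0.86 ± 0.15 with slide as a block and 1.09 to 1.43 within 2 slides (adjusted p = 6.69e-25, and adjusted p = 0.000141 with an estimated correlation). CC chemokines had 6 of 17 higher, among them Ccl9 (1.36 ± 0.27) and Ccl8 (1.29), and 8 when adjusted over the list alone. The mean of CC chemokines was 0.66, 0.61 ± 0.17 with slide as a block and 0.82 to 0.85 within slides (adjusted p = 5.03e-08, and adjusted p = 0.0158 with an estimated correlation). Inflammatory cytokines had 2 of 15 higher (3 when adjusted over the list alone). These were Csf2 (1.34 ± 0.27), a growth factor for granulocytes and macrophages, and Il1rn (0.94 ± 0.17), which blocks the receptor of interleukin-1. Cytokines had a mean of 0.31, and 0.36 to 0.39 within slides (adjusted p = 0.000181, and adjusted p = 0.0158 with an estimated correlation). Neutrophil markers had 2 of 18 higher, Mmp8 (1.26) and Clec4d (1.07), and 8 when adjusted over the list alone (adjusted p = 3.59e-06, and adjusted p = 0.167 with an estimated correlation). Interferon response genes had 3 of 18 higher, Oas1a (0.96), Oasl1 (0.79) and Ifih1 (0.46), and 8 when adjusted over the list alone (adjusted p = 1.73e-08, and adjusted p = 0.177 with an estimated correlation).

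Endothelial markers had 1 of 15 lower on day 28 at 162 µg (1 when adjusted over the list alone). Their mean was -0.32, -0.27 with slide as a block and -0.26 to 0.05 within slides (adjusted p = 9.08e-07, and adjusted p = 0.177 with an estimated correlation). Alveolar type 1 markers had 0 of 8 past the test, with a mean of -0.31, -0.19 with slide as a block and -0.12 to 0.10 within slides. As a list they had adjusted p = 0.000993, and adjusted p = 0.213 with an estimated correlation. Both means rested largely on 162 µg replicate 1, with an endothelial mean of 3.31 where the controls lay between 4.29 and 4.62. Without it the endothelial mean change was -0.10 and that of alveolar type 1 markers -0.07. Heart muscle markers had a mean of 0.75 in this comparison (adjusted p = 0.0765). Single members of other lists that passed were Itih4 (0.90), Cxcl9 (0.79), C1ra (0.47), Tgfbi (0.76) and Cd86 (0.42). Within the older protocol (1 array each, the treated one being 162 µg replicate 1), Itih4 turned to -0.12 and Tgfbi to -0.10. Cell cycle genes (mean 0.09, adjusted p = 0.5) and extracellular matrix genes (mean 0.06, median 0.03, test pointing down, adjusted p = 0.844) did not pass.

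The day 28 test at 162 µg passed 228 genes, 219 higher and 9 lower (2036 at an unadjusted p below 0.05, and 140 with slide as a block). The count was 92 without 162 µg replicate 4, 96 without replicate 5, 134 without replicate 3 and 130 without control replicate 2. It was 109 with median centring, 99 with uneven spots kept, 116 without the 7 arrays with uneven backgrounds, 533 with array weights and 8 within the older protocol, and split into 165 higher and 31 lower with Agilent's processed signals. Of the 34 genes chosen by the rule, 20 lost the threshold with slide as a block. Saa3 (0.252) and Ccl2 (0.0755) were among them, as were the 6 falls named above (adjusted p of 0.084 to 0.24) and Slfn4, Proz, Ccdc122 and Kcnj10 (0.0597 to 0.324). The same held for Cxcl9 (0.188), Ccl8 (0.191), Csf2 (0.0545), Clec4d (0.0643), Oas1a (0.0803), Oasl1 (0.0632), Ifih1 (0.0637) and Cd86 (0.208).

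At 54 µg on day 28 (n = 5 each) limma passed 0 genes (886 at an unadjusted p below 0.05), and at 18 µg (n = 6, against 5) 0 genes (1262). Slc26a4 stood at 1.15 ± 0.47 and 1.03 ± 0.45 at these doses (adjusted p of 1 and 0.823). Lcn2 stood at 0.53 and 0.74, Gpnmb at 0.19 and 0.35 and Spp1 at 0.02 and 0.22. At 18 µg, heart muscle markers had a mean of 1.83 ± 0.60, 2.02 with slide as a block and 0.06 to 2.75 within 2 slides. Of its 10 measured members, 9 were higher when adjusted over the list alone and 0 over all genes (adjusted p = 2.17e-13, and adjusted p = 0.215 with an estimated correlation). Secretory airway markers moved with them, with a mean of 1.17 and 3 of 12 higher when adjusted over the list alone (adjusted p = 4.02e-05, and adjusted p = 0.515 with an estimated correlation). At 54 µg, the heart muscle mean was 0.79 (adjusted p = 0.013, and adjusted p = 0.798 with an estimated correlation). Beside it stood neutrophil markers at 0.37 (adjusted p = 2.12e-05) and ciliated cell markers at 0.36 (adjusted p = 6.28e-06), both with adjusted p = 0.514 with an estimated correlation.

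Between 162 and 54 µg on day 28 (n = 5 each), Spp1 was 4.86-fold higher at the larger dose (2.28 ± 0.45, adjusted p = 0.00472), and Lcn2 3.48-fold (1.80 ± 0.45, 0.0489). Ccl2 was 3.39-fold higher (1.76 ± 0.40, 0.0231) and Gpnmb 3.37-fold (1.75 ± 0.22, 1.6e-06), while Bex2 fell by 1.1 (0.00559). Macrophage markers had 6 of 18 higher, or 13 higher and 1 lower when adjusted over the list alone. Their mean was 0.70, with 0.36 to 1.07 within 3 slides (adjusted p = 1.4e-23, and adjusted p = 0.00023 with an estimated correlation). Inflammatory cytokines had 1 of 15 higher and 3 when adjusted over the list alone (adjusted p = 1.71e-05, and adjusted p = 0.00603 with an estimated correlation). In all, 67 genes passed, 64 higher and 3 lower (1413 at an unadjusted p below 0.05, and 25 with slide as a block). The count ran from 16 without 162 µg replicate 4 to 156 without 162 µg replicate 1 and was 0 when only these groups entered the fit. The Lcn2 call was kept in 9 of 32 other fits, lost in 22 and reversed in 1, at -0.0251, within the older protocol, whose only 162 µg array on day 28 is replicate 1. With slide as a block, Spp1 (0.0628), Lcn2 (0.302) and Ccl2 (0.197) lost the threshold.

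**Figure D3:**
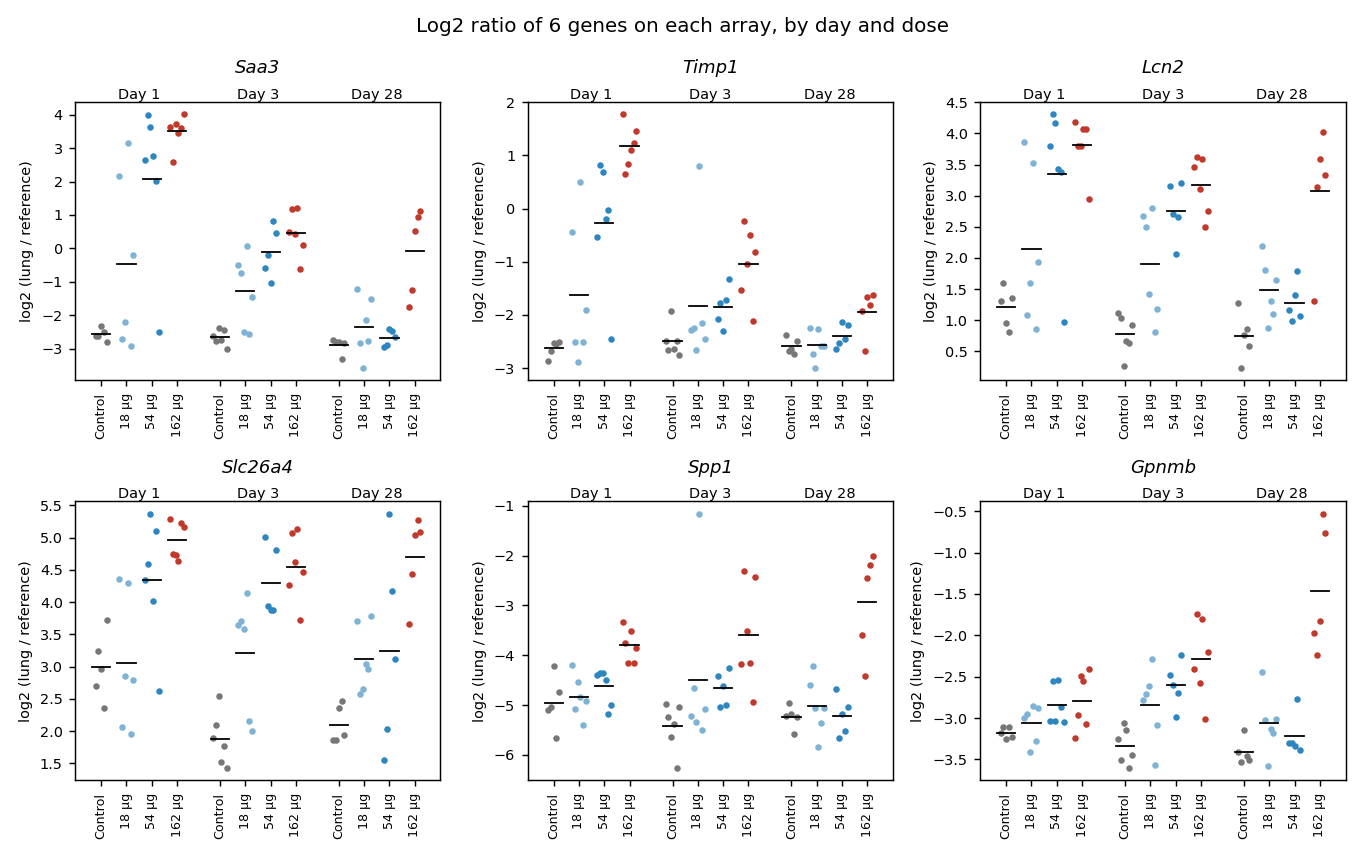
Log2 ratio of lung to reference RNA (y axis) of Saa3, Timp1, Lcn2, Slc26a4, Spp1 and Gpnmb on each array (points) by day and dose (x axis), with lines at group means. The mean of Saa3 at 162 µg is 3.50 on day 1, 0.46 on day 3 and -0.08 on day 28, and that of Gpnmb is -2.79, -2.29 and -1.47.

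Whether the effect of 162 µg differed between days was tested directly. From day 1 to day 3 the effect fell for Saa2 (by 2.23 ± 0.46, adjusted p = 0.0423), Serpina3m (fell by 1.48 ± 0.31, 0.0423), Hpx, which binds free haem (fell by 1.38 ± 0.29, 0.0487), and Pbp2 (fell by 1.26 ± 0.25, 0.0312). These calls were lost in many of 45 other fits, since Hpx kept its call in 13, Saa2 in 18, Serpina3m in 20 and Pbp2 in 26. Saa2 (adjusted p = 0.0668), Hpx (0.147) and Pbp2 (0.0716) lost the threshold with slide as a block. From day 1 to day 28 the effect rose for Gpnmb (1.56 ± 0.31, adjusted p = 0.00726) and Ctsd, a lysosomal protease (1.05 ± 0.24, 0.0336). It also rose for Siglec1, a macrophage receptor (1.04 ± 0.19, 0.00365), and Mpeg1, a pore-forming protein of macrophages (1.00 ± 0.21, 0.0144). Over the same interval the effect on Timp1 fell by 3.16 ± 0.63 (0.00746), that on Saa1 fell by 2.90 ± 0.65 (0.0309, and 0.0652 with slide as a block), that on Saa2 fell by 2.37 ± 0.48 (0.0117) and that on Mt2 fell by 2.11 ± 0.45 (0.0144). The acute phase list fell by 1.11 from day 1 to day 3, with 3 of 17 lower and 9 when adjusted over the list alone (adjusted p = 1.47e-20, and adjusted p = 0.00669 with an estimated correlation). To day 28 it fell by 1.21, with 2 of 17 lower and 10 when adjusted over the list alone (adjusted p = 1.77e-15, and adjusted p = 0.035 with an estimated correlation). For macrophage markers the difference to day 28 was 0.45, with 1 of 18 higher and 3 when adjusted over the list alone (adjusted p = 0.00106, and adjusted p = 0.468 with an estimated correlation).

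In all, 7 genes differed between days 1 and 3, 2 higher and 5 lower (858 at an unadjusted p below 0.05), and 33 between days 1 and 28, 20 higher and 13 lower (2332). Without single mice these counts ran from 0 to 10 and from 19 to 46. With median centring they were 0 and 4, and with slide as a block 7 and 50.

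Genes that passed on several days at 162 µg overlapped more than independent draws would. Of the genes higher on day 1, 153 were also higher on day 3 (11 for independent draws, one-sided Fisher's exact p = 8.9e-137). On days 1 and 28, 62 genes were higher (6.30 for independent draws, exact p = 6.05e-44), and on days 3 and 28 also 62 (3.96, exact p = 1.38e-56). Each day had its own controls, but the days shared slides and the same fit, so their calls were not independent. The exact p treats genes as independent and does not measure the spread between mice. For lower genes the overlap was 44 between days 1 and 3 (2.40, exact p = 1.27e-43) and 0 between either and day 28 (0.161 and 0.0568 for independent draws).

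Controls of day 28 and day 1 (n = 5 each) were compared as the background. By limma 0 genes passed (1180 at an unadjusted p below 0.05), and 0 passed with slide as a block. Heart muscle markers had a mean of -1.27, with 0 of 10 past the test and 2 lower when adjusted over the list alone (adjusted p = 2.68e-06, and adjusted p = 0.452 with an estimated correlation). Adipose markers had a mean of -1.31, or -0.87 without day 1 control replicate 5 (adjusted p = 0.000128, and adjusted p = 0.452 with an estimated correlation). Secretory airway markers had a mean of -0.72 (adjusted p = 0.0186, and adjusted p = 0.618 with an estimated correlation). The heart muscle mean per array ran from -0.10 to 0.14 in day 28 controls and reached 3.95 on day 1 at 162 µg and 3.85 on day 28 at 18 µg.

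**Figure D4:**
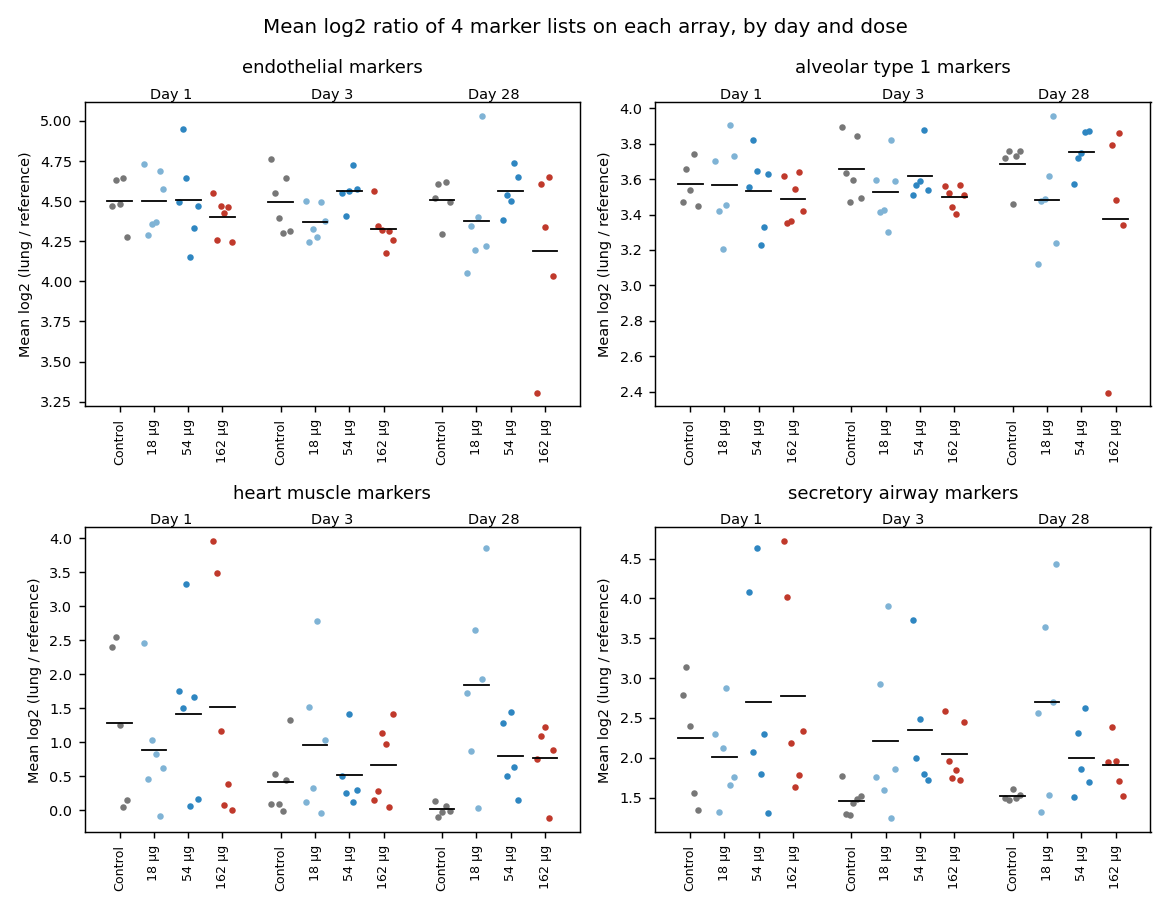
Mean log2 ratio of lung to reference RNA (y axis) of endothelial, alveolar type 1, heart muscle and secretory airway markers on each array (points) by day and dose (x axis), with lines at group means. The day 28 control mean of heart muscle markers is 0.01 and that at 18 µg is 1.84, and the lowest point of the endothelial list, 3.31, is a mouse given 162 µg on day 28.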

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

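Both explanations weighed in this part were written down before their results were seen, and the splits of the samples were planned. The range of the marker difference on the other arrays was added after it was seen.

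In 13 of 156 groups of arrays tested over 13 measures, a single array lay far from the rest of its group; chance gives about 1 in 20 groups. On day 1 at 54 µg, replicate 6 had log2 ratios of -2.51 for Saa3 (the others 2.01 to 3.98), 0.97 for Lcn2 (3.39 to 4.31) and 0.17 for the macrophage list (0.65 to 0.77). On day 1 at 162 µg, replicate 6 had an Lcn2 ratio of 2.94 (3.80 to 4.19). On day 3 at 18 µg, replicate 4 had ratios of -1.16 for Spp1 (-5.50 to -4.66) and 0.80 for Timp1 (-2.65 to -2.15), and among day 3 controls replicate 3 had a Timp1 ratio of -1.94 (-2.75 to -2.49). Day 28 arrays that stood apart were 54 µg replicate 4 for Gpnmb at -2.77 (-3.38 to -3.30), control replicate 4 for Saa3 at -3.31 (-2.83 to -2.74), and 162 µg replicate 2 for Timp1 at -2.67 (-1.92 to -1.63). Among lists of cell markers, alveolar type 1 markers were at 3.88 on day 3 in 54 µg replicate 4 (3.51 to 3.59) and at 3.46 in day 28 control replicate 3 (3.72 to 3.76), and endothelial markers at 5.03 on day 28 in 18 µg replicate 5 (4.05 to 4.40).

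The effect of 162 µg differed between days for several genes by the interaction test in limma. Between days 1 and 3 the difference was -2.23 for Saa2, -1.48 for Serpina3m, -1.38 for Hpx and -1.26 for Pbp2. Between days 1 and 28 it was 1.56 for Gpnmb, 1.05 for Ctsd, 1.04 for Siglec1 and 1.00 for Mpeg1, where Siglec1 had effects of -0.05 on day 1 and 0.99 on day 28. It was -3.16 for Timp1, -2.90 for Saa1, -2.37 for Saa2 and -2.11 for Mt2, where Timp1 had effects of 3.80 on day 1 and 0.65 on day 28. For the acute phase list the differences were -1.11 (adjusted p = 0.00669 with an estimated correlation) and -1.21 (adjusted p = 0.035).

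For each count of genes, 100 splits of the same arrays into groups of the same sizes were drawn, the real one included. No share below 1 in 100 can be seen with them. Arrays moved freely over slides and protocols, so batches that arrays share were not weighed. Chance is argued against for 162 µg against control on day 1 (1 split as large, 991 genes). The highest other gave 654, in a split that parted all but 1 of the 11 arrays as the real one did. Chance is also argued against on day 3 (1 split, 518, highest other 70) and on day 28 (1 split, 228, highest other 58). The same holds for 54 µg on day 1 (1 split, 115, highest other 86) and day 3 (1 split, 22, highest other 1), and for the differences of the effect between days 1 and 28 (1 split, 33, highest other 7). For 18 µg on day 1, 4 splits gave as many as the single gene found (highest other 1), and for the difference between days 1 and 3, 4 splits gave as many as 7 genes. There the highest other split gave 46, which points to a structure of the samples whose source was not tested. Chance cannot be excluded for 162 against 54 µg on day 1 (11 splits as large, 19 genes, highest other 170) or on day 28 (5 splits, 67, highest other 120). The 170 genes again point to a structure of the samples, whose source was not tested either. With 0 genes found, all 100 splits were as large for 18 µg on day 3 (highest other 1), 54 µg (1) and 18 µg (3) on day 28, 162 against 54 µg on day 3 (14) and the controls of days 28 and 1 (9).

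One pattern weighed here is that on the array of day 28, 162 µg replicate 1, markers of lung cells were low, with means of 3.31 for endothelial, 2.39 for alveolar type 1 and 2.71 for alveolar type 2 markers. Compressed log ratios on that array stay open as an explanation. The median deviation of 426 genes outside the lists with high ratios was -0.59 (-0.28 to 0.59 on the other arrays), and that of 85 genes with low ratios was 0.69 (-0.58 to 0.45), as compression would give. Fewer alveolar and endothelial cells in that lung also stay open. Against 50 other genes of the same mean ratio, the 35 markers differed by a median of -0.44 (-0.36 to 0.41 on the other 66 arrays), which lies between the -0.5 set beforehand for fewer cells and the 0.25 around 0 set for none. The median deviation of these markers from the rest of the group was -1.24 on this array. It was low on the other arrays of its slide too, at -0.47 (18 µg replicate 1) and -0.35 (54 µg replicate 1). An effect of the slide was not tested here and stays open as well. Without the array of 162 µg replicate 1, the comparison of 162 with 54 µg on day 28 gave 156 genes in place of 67.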

How the results depend on the processing

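In all, 20 alternatives, with each mouse left out among them, were chosen before the data were examined. The fits with uneven spots kept for the background correction, with each protocol alone, and without the slide scanned first, the 7 arrays with uneven backgrounds or the 5 arrays highest in heart muscle markers were chosen after the data were seen. Arrays limit what can be seen through signal over background, since 51.3 to 75.0% of spots were well above it. The causes of the changes below were not tested unless fewer arrays or another threshold show them. Counts are given as D1, D3 and D28 for the day and the dose in µg against its control. There, 162v54 is the test between doses, and D3-D1 and D28-D1 are the differences of the 162 µg effect.

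Without background correction the counts were 0 for D1 18 and 13 for D3 54. Agilent's processed signals gave 1828 for D1 162, 13 for D1 18, 801 for D3 162, 9 for D3 54, 0 for D3-D1 and 4 for the controls of days 28 and 1. Up and down split there as 91 and 34 for D1 54, 20 and 4 for D1 162v54 and 165 and 31 for D28 162. Median centring gave 72 for D1 162 (69 and 3), 19 for D1 54, 0 for D1 18, 45 for D3 162, 4 for D3 54, 109 for D28 162, 4 for D1 162v54, 18 for D28 162v54, 0 for D3-D1 and 4 for D28-D1 (3 and 1). There the median change of all genes was 0.12 for D1 18, 0.15 for D28 162 and 0.14 for D28-D1, against -0.00175, 0.0198 and 0.0230. The authors' values gave 0 for D1 18 and 12 for D3 54, with 11 up and 14 down for D28-D1. With uneven spots kept for the background correction, and those with only an uneven background kept throughout, the counts were 295, 31 and 0 for D1 162, 54 and 18, 191 and 8 for D3 162 and 54, 99 for D28 162, 2 for D1 162v54, 28 for D28 162v54, 0 for D3-D1 and 4 for D28-D1. With no filter D3-D1 was 3.

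With slide as a fixed block the counts were 26 for D1 18, 68 for D3 54, 140 for D28 162, 40 for D1 162v54, 25 for D28 162v54 and 50 for D28-D1. With slide as a random block (correlation 0.125) they were 13 for D1 18, 61 for D1 162v54, 11 for D3-D1 and 70 for D28-D1. With scan day they were 3 for D1 18, 986 for D3 162, 119 for D28 162, 59 for D1 162v54 and 63 for D28-D1. Array weights (0.297 to 2.15) gave 11 for D1 18, 172 for D3 54, 533 for D28 162, 2 for D28 54, 226 for D28 162v54, 132 for D28-D1 and 12 for the controls. A fold of 1.5 left 284, 66 and 0 on day 1 (162, 54 and 18 µg), 213 for D3 162 and 138 for D28 162. An adjusted p below 0.1 gave 1600, 288 and 12 on day 1, 1007 and 44 for D3 162 and 54, 352 for D28 162, 57 for D1 162v54, 117 for D28 162v54, 11 for D3-D1 and 82 for D28-D1. When only the groups compared entered the fit, the counts were 506 for D1 162, 0 for D1 54, 27 for D1 18, 100 for D3 54, 0 for D1 162v54, 0 for D28 162v54 and 11 for D3-D1.

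Within the older protocol, with 1 control array per day, the counts were 3, 0 and 0 on day 1, 0 and 0 for D3 162 and 54, 8 for D28 162, 3 for D1 162v54, 34 for D28 162v54, 0 for D3-D1 and 1 for D28-D1. Within the newer protocol they were 243 for D1 54, 0 for D1 18, 46 for D3 162, 1 for D3 54, 5 for D1 162v54, 13 for D28 162v54, 2 for D3-D1 and 20 for D28-D1. Without the slide scanned first D1 18 was 0 and D3-D1 3. Without the 7 arrays the counts were 613, 46 and 0 on day 1, 319 and 12 for D3 162 and 54 and 116 for D28 162. Without the 5 arrays highest in heart muscle markers they were 63 for D1 54, 36 for D3 54, 83 for D1 162v54, 12 for D3-D1 and 66 for D28-D1. The counts of 0 for D3 18, D28 18 and D3 162v54 stayed 0 under every alternative run, except that D28 18 reached 1 with a single mouse left out.

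With each mouse left out in turn, D1 162 ran from 643 (without control 4) to 1096. D1 54 ran from 33 (without 54 µg replicate 2) to 365 (without replicate 6), with 57, 42 and 49 without controls 1, 3 and 4 and 44 and 36 without replicates 3 and 4. D1 18 ran from 0 (without controls 2, 3 or 4 or 18 µg replicates 1, 2, 3, 4 or 6) to 9 (without control 5). D3 162 ran from 140 (without 162 µg replicate 4) to 765, with 175 without replicate 2 and 293 and 331 without controls 2 and 3. D3 54 ran from 6 (without 54 µg replicates 2 or 5) to 31, with 8 and 12 without replicates 1 and 4, 11 without controls 2 or 4 and 10 without control 5. D3 18 and D3 162v54 stayed at 0. D28 162 ran from 92 (without 162 µg replicate 4) to 307, with 134 and 96 without replicates 3 and 5 and 130 without control 2. D28 54 and D28 18 ran from 0 to 1 (without control 1, and without 18 µg replicate 3). D1 162v54 ran from 5 (without 54 µg replicate 4) to 38 (without 162 µg replicate 2), with 11, 29, 29 and 6 without 54 µg replicates 1, 2, 3 and 6 and 6 and 10 without 162 µg replicates 5 and 6. D28 162v54 ran from 16 (without 162 µg replicate 4) to 156 (without replicate 1), with 136, 37 and 21 without replicates 2, 3 and 5 and 41, 33, 112 and 23 without 54 µg replicates 1, 2, 4 and 5. D3-D1 ran from 0 to 10 and moved by over 1.5 times without 17 of 23 mice. D28-D1 ran from 19 (without day 1 control 2) to 46, with 21 without day 28 control 3, and the controls of days 28 and 1 ran from 0 to 1 (without day 28 control 3).

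Directions turned in these cases. With Agilent's processed signals Pigr was at -0.12 on day 1 and -0.40 on day 3 at 162 µg, and the skeletal muscle list on day 28 at 162 µg pointed up (adjusted p = 0.0209). With uneven spots kept for the background correction, the cell cycle list turned for D1 54 (adjusted p = 0.693) and D28 162 (0.0181) and the endothelial list for D3 162 (0.459). Within slides the D28 54 means of the cell cycle and extracellular matrix lists were 0.0472 and 0.0746. Within the older protocol Fbln1 was at 0.0477 (D1 162), Itih4 at -0.12 and Tgfbi at -0.10 (D28 162) and Lcn2 at -0.0251 (D28 162v54), where replicate 1 is the only 162 µg array of day 28. The alveolar type 2 list turned for D28 162 within the newer protocol (adjusted p = 0.0364), without the slide scanned first (0.0200) and without 162 µg replicate 1 (0.0233), and for D28 162v54 within the newer protocol (0.542) and without that replicate (0.259). Each of these fits leaves that replicate out. Over the mice left out, its adjusted p ran from 0.00588 to 0.471 for D28 162 and from 2.8e-06 to 0.259 for D28 162v54. Without the 5 arrays, the heart muscle list turned for D1 162 (0.00122), D1 162v54 (0.0268) and D3-D1 (1.44e-05), and the secretory list for D3-D1 (0.00135).

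With an estimated correlation, 137 of 450 list results lost their call. The other 313 kept their side of the threshold, but these include the lists that passed in neither test. With fry, 109 lost their call and 2 gained one. A list call that held with an estimated correlation was kept under every other alternative run. The refits of those alternatives used the preset correlation, and the estimated one was not rerun in them. Over the leave-one-out fits of 166 named genes, 1526 values kept direction and threshold and 439 lost the threshold alone. Tallies of other fits include an adjusted p below 0.1 and quantile normalization between arrays, which could not end a call. Over all other fits, 21 of the 166 lost their call at least as often as they kept it. Among them were Ndst1 (9 of 32), Mmp3 (11), Flt1 (12), Cxcl9 (14) and Calcrl (15) for D28 162, Kcnj10 there (11 of 31), Retnlb (10 of 33), Cxcl1 (14 of 34) and Timp1 (17 of 34) for D3 162, Tk1 (12 of 33), Cfi, Retnlg and Cxcr2 (16 each) for D1 162, Mid1ip1 (14 of 33) for D1 54 and Gnal (15 of 33) for D1 18.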

Other observations

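Of the tests in this part, those of more ciliated cells, of centriole amplification genes, of resident alveolar macrophages and of slide for the macrophage pattern were chosen after the results were seen, as were the genes named here.

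At 162 µg, 38 genes were higher on all of days 1, 3 and 28, 31 of them with symbols. Beside Saa3, Lcn2, Slc26a4, Noxo1 and the chemokines Ccl2, Ccl8, Ccl9 and Ccl12, they included Ch25h (2.19 ± 0.28, 1.66 ± 0.26 and 1.44 ± 0.29 on the 3 days). Slpi, an inhibitor of neutrophil proteases, stood at 1.21, 1.14 and 1.44, and Fxyd4, a regulator of the sodium pump, at 1.27, 1.47 and 1.22. Muc4, a membrane mucin, stood at 0.96, 0.87 and 1.01, Steap4, a metal reductase, at 0.92, 0.69 and 0.88, and Vnn3 at 1.00, 0.97 and 1.05. The myeloid genes Clec5a (1.05, 0.79 and 1.33), Ms4a6d (0.74, 0.90 and 1.01), Lilrb4a (0.53, 0.74 and 1.00) and Wfdc17 (1.24, 1.27 and 1.94) were among them. So were Il4i1, an amino acid oxidase of myeloid cells (0.70, 0.59 and 0.80), and Arg2, a mitochondrial arginase (0.86, 0.75 and 1.02). Ptgs1, a prostaglandin synthase (1.25, 0.80 and 0.78), and F10, a clotting factor (0.68, 0.67 and 0.69), belonged to them too. With slide as a block, 11 of the 38 genes passed on each day, 12 on 2 days, 8 on 1 day and 7 on none. Of the genes named here, Clec5a (0.97, 0.77 and 1.40), Noxo1 (1.31, 1.53 and 1.70), Slpi (0.93, 0.89 and 1.28), Lcn2 and Ms4a6d passed on each day. Muc4 (adjusted p of 0.238, 0.145 and 0.306), Arg2 (0.0903, 0.133 and 0.137), Vnn3 (0.0783, 0.0585 and 0.24), Il4i1 (0.0655, 0.0977 and 0.11) and Ccl8 (0.15, 0.0783 and 0.191) passed on none. Day 1 was lost for Slc26a4 (0.0557), Wfdc17 (0.0568), Lilrb4a (0.0612) and Ccl9 (0.0549). Day 28 was lost for Saa3 (0.252), Ccl2 (0.0755), Ch25h (0.0643), Fxyd4 (0.0734) and Ptgs1 (0.084). Steap4 (0.17 and 0.221) and Ccl12 (0.134 and 0.135) lost days 3 and 28, and F10 (0.0543 and 0.21) lost days 1 and 28.

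Lysosome genes, a list written after the first results were seen, had 5 of 28 measured members higher on day 28 at 162 µg and 14 when adjusted over the list alone. Examples were Atp6v0d2, a subunit of the proton pump (0.55, adjusted p = 0.00019), Ctsb (0.58) and Cd63 (0.56). On day 3 there were 4 higher, including Npc2 (0.60), and 12 when adjusted over the list alone, with a mean of 0.20 (adjusted p = 0.0563 with an estimated correlation over 9 tests of such lists). On day 1 there were 2 higher and 1 lower, with a mean of 0.06 (adjusted p = 0.705). Of 12 resident alveolar macrophage genes, 2 were lower on day 1, Fabp1 (-0.94) and Krt79 (-0.68), with a list mean of -0.27 ± 0.11 (adjusted p = 0.199).

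On day 3 at 162 µg, Ccno (1.5 ± 0.22), Ccna1 (1.17 ± 0.16) and Deup1 (0.71 ± 0.13), genes of cells that build many cilia, rose on 6 of 6 arrays each, and stood at 0.39, 0.09 and 0.08 on day 1 and -0.24, 0.06 and 0.03 on day 28. The interaction test of the 162 µg effect between days 1 and 3 called none of these 3 genes. A difference between days 3 and 28 was not tested. More ciliated cells in the samples as the whole cause are argued against by the ciliated cell list, whose mean was 0.0859 ± 0.16. Foxj1 stood at 0.43 (adjusted p = 0.247), and a smaller increase of ciliated cells stays open. Slide as the whole cause is argued against by a mean of 1.07 ± 0.17 of the 3 genes with slide as a block (1.13 ± 0.15 without). Of 16 other centriole amplification genes listed, 9 were measured. A wider rise is argued against for these 9 by their mean of 0.0586 ± 0.05 (adjusted p = 0.717 with an estimated correlation). The unmeasured members, and a rise confined to few cells of the lung, were not tested. A link to the cell cycle rise stays open, since over 67 arrays, as deviations from group means, the 3 genes went with the cell cycle list at r = 0.327 (permutation p = 0.0669, adjusted 0.0669) and rho = 0.164 (permutation p = 0.245, adjusted 0.332), with r = 0.226 without the 2 farthest arrays and 0.453 within slides.

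On day 28 at 162 µg, macrophage markers rose unequally, since Spp1 (2.30), Gpnmb (1.94), Trem2 (1.53) and Ctsk (1.43) passed while Chil3 (0.00), Csf1r (0.13), Siglecf (0.25) and Marco (0.35) did not. Slide as the whole cause is argued against by a list mean of 0.86 ± 0.15 with slide as a block, against 0.87 ± 0.13 without. More macrophages of the resident alveolar kind stay open, since their list had a mean of 0.20 ± 0.11 over 12 members (adjusted p = 0.472). This mean did not reach the share of the macrophage list's mean that was set as the mark. With its error, it was not low enough to argue against a smaller rise either. Chil3, Siglecf and Marco are 3 of these 12, and the other 9 had a mean of 0.19 ± 0.10. A rise of lysosome genes had the values set for it, with a mean of 0.31 ± 0.06 (adjusted p = 0.00192 with an estimated correlation). That test asked only whether these genes rose, so it cannot tell why the macrophage markers rose unequally. The lysosome rise is a hypothesis found and tested on the same data.

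In all, 3 relations were tested across the 67 arrays, as deviations from group means. Secretory airway markers went with heart muscle markers at r = 0.80 (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted 3e-05) and rho = 0.723 (adjusted 3e-05). Without the 2 farthest arrays r was 0.754, and within slides 0.771. Acute phase genes went with heart muscle markers at r = 0.336 (permutation p = 0.0152, adjusted 0.0228), while rho was 0.130 (permutation p = 0.332, adjusted 0.332). Without the 2 farthest arrays that r was 0.302, and within slides 0.260.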
